A study of Mus musculus with 8 samples.

How the data were processed

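RNA was measured in 8 libraries of immortalised mouse skin fibroblasts, 2 in each of 4 groups given by the labels: WT or KO cells, at 21% or 1% oxygen for 24 hours. Per the labels' protocols, total RNA was taken with a miRNeasy kit and the libraries were made with a New England Biolabs small RNA set for the SOLiD sequencer. The deposited table holds a score per gene and library: per its name, the authors' normalised read counts. From the values, these are whole numbers with a lowest value of 1 in every library, and 2240 of the 17091 features are at 1 in all 8 libraries. The aligner, the counting program, the genome build, the use of strand and the normalization method are not given in the sources used here. Genes that overlap, antisense partners and near-identical copies (histone genes, ribosomal protein genes with pseudogenes) may share reads, so their values are uncertain. No pair of libraries held identical values. Names of 26 features were ones that a spreadsheet had turned into dates, and 2 names were duplicated. The number of sample columns left unused was 0.

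The totals of the deposited values ran from 7.93 M to 8.68 M per library, but normalised totals do not show depth. Depth was estimated from the spacing of the low values, which gives what 1 read is worth in each library (0.674 to 1.384). Dividing by it gave an estimated 6.26 M to 11.74 M reads assigned to genes. On 4 simulated libraries the largest error of this factor was 0.002. Rounding hides the reads themselves, so no count model was run, and with whole reads not recovered the depth is an estimate only. A value near 10 rests on about 10 reads, and counting error alone is then large.

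The plan written before the data were examined named the tests, the alternatives, the gene lists and the rule for naming genes. It called for limma-trend if the values were normalised, as they are, and for a count test if whole reads could be had, which the unit of the values ruled out. Values were taken as log2(value + 1), so fold changes understate those of low genes. Genes with a value of at least 10 in at least 2 of the 8 libraries were tested, which kept 12107 features and left 4984 untested. A model with the 4 groups was fitted to all 8 libraries with limma (version 3.58.1, R 4.3.3, statmod 1.5.0), without a replicate term, and contrasts gave 5 planned comparisons: hypoxia against normoxia in WT and in KO, KO against WT at each oxygen level, and the difference of the hypoxia responses (KO minus WT). Moderated tests had 10.2 degrees of freedom, and p values were adjusted by Benjamini and Hochberg over all tested genes within a comparison, with a threshold of 0.05. All adjusted p values for genes are from limma and two-sided. An exact test of 2 libraries against 2 cannot give a p below 0.333, so every call rests on the spread shared over the 4 groups. Both pooled comparisons (hypoxia against normoxia over both genotypes and KO against WT over both oxygen levels) were added after the data were seen.

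The test was checked on simulated data with 200 changed genes in the WT hypoxia comparison (11946 genes). It recovered 0 of 50 genes changed 1.5-fold, 7 of 50 changed 2-fold (14%), 30 of 49 changed 4-fold (61.2%) and 40 of 50 changed 8-fold (80%), with 5 unchanged genes called. In the KO hypoxia comparison, where the simulation held no change, 0 genes were called. Genes were drawn independently, with no trend with transcript length and no library that stood apart. False calls from such features of the real libraries were therefore not measured.

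Gene lists (33 lists, 954 entries) were tested with limma's camera at a preset correlation of 0.01, adjusted over the 32 lists with at least 3 tested members within a comparison. Camera with an estimated correlation and fry were run beside it. The lists were HIF-responsive genes, glycolysis enzymes and transporters, nuclear-encoded OXPHOS subunits, mitochondrially encoded genes, iron-sulfur cluster and mitochondrial assembly genes, miR-210 targets from the literature, genes flanking Mir210, S phase and DNA replication, G2/M and mitosis, p53 targets, interferon-stimulated genes, antigen presentation class I, NF-kB and inflammatory mediators, collagens and ECM proteins, collagen-modifying and crosslinking enzymes, contractile and TGF-beta responsive genes, matrix metalloproteinases and inhibitors, ATF4 and the unfolded-protein response, cholesterol biosynthesis, NRF2 and oxidative stress, autophagy and mitophagy, cytosolic ribosomal proteins, replication-dependent histones, immediate-early genes, Hox genes, positional and lineage fibroblast genes, Y-linked genes and Xist, and markers of macrophages and leukocytes, endothelium, keratinocytes and epithelium, Schwann cells and melanocytes, adipocytes, and skeletal and smooth muscle. The list of mitochondrially encoded genes had 0 of its 15 genes in the table and was not analysed here.

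The genes named are Mir210, then per comparison up to 10 genes per direction with the largest change among those past the threshold with separated groups and a mean value at or above the median of 250.2, or all past the threshold where few passed. Where none passed, the 3 genes with the smallest p per direction among those at or above that median are given as values. The plan did not say whether the median applied to this case, and genes under it can have a smaller p. Up to 4 members per list with the smallest p may be named, and any member of the lists for HIF, glycolysis, miR-210 targets and genes flanking Mir210. Genes named outside this rule were chosen after their values were seen, and the text says where. Gene positions, transcript lengths and 3' UTRs are from GENCODE M21 on GRCm38, to which 16783 features (98.2%) were matched by name. The 3' UTRs of 44761 transcripts were taken from the annotation, and 100% of them followed a stop codon. A gene had a miR-210 seed site where its 3' UTR held ACGCACA, the complement of bases 2 to 8 of miR-210-3p.

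The alternatives chosen beforehand were no filter, a minimum of 50, pseudocounts of 0.5 and 5, rescaling by the median of ratios, quantile normalization, a fit of the 4 libraries compared alone, array weights, a robust spread model, a replicate block, a minimum log2 fold change of 1, each library left out in turn, and, for seed sites, 8-mer sites and genes matched on UTR length (the 5 nearest genes per gene with a site). Added after the data were seen were a block within each genotype, removal of each library's trend with transcript length (loess, span 0.5), leaving out small RNAs, a pseudocount of 0, and leaving out libraries that stood apart. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.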

Results

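Gene expression was measured by RNA sequencing in immortalised fibroblasts, skin cells adapted to continuous culture, derived from wild-type C57BL/6 mice (WT) or from mice labelled mir210lox/lox, whose libraries are named KO. A lox site marks DNA that the Cre recombinase can cut out, and the labels name no Cre treatment, so KO is used here as the name of the group. Cells were kept for 24 hours at 21% oxygen (normoxia) or at 1% oxygen (hypoxia), with 2 libraries in each of the 4 groups and 8 in all. miR-210 is a microRNA whose gene is switched on by HIF, the transcription factor of the low-oxygen response, and the design asks how cells respond to low oxygen with and without it. All values are the authors' normalised read counts. Estimated assigned reads ran from 6.26 M in KO hypoxia replicate 1 to 11.74 M in KO normoxia replicate 2. The labels do not say that the libraries of a group came from separate cultures, so p values measure only the spread between these libraries, which may be technical.

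Mir210, the targeted gene, was at the lowest deposited value, 1, in all 8 libraries, WT hypoxia included. It lies on chromosome 7 at 141221384 to 141221493 on the minus strand (GRCm38), an annotated microRNA gene of 110 bases, 2725 bases past the end of Rassf7 and 7290 bases before Phrf1. At this floor its value does not check the labels. Rassf7, a Ras-association domain gene, was at 220.5 ± 36.1 in WT normoxia, 325 ± 17.0 in WT hypoxia, 139 ± 9.90 in KO normoxia and 162 ± 25.5 in KO hypoxia (mean ± SD, n = 2 each). None of its comparisons passed the test over all genes.

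The libraries of a group differed from each other, in part along lines that also move with oxygen. Pearson correlations of log2 values across genes were 0.954 to 0.985 within groups and 0.946 to 0.988 between groups. WT hypoxia replicate 2 stood apart on the component with 30% of the variance (45.9, the other libraries between -27.3 and 26.5). KO normoxia replicate 1 did so on that with 25.4% (44.9, the others between -30.6 and 14.5), with both WT libraries numbered 2 lowest (-30.6 and -23.9). The component with 18.1% parted all normoxia libraries (6.9 to 30.3) from all hypoxia libraries (-28.9 to -10.8). In WT hypoxia replicate 2 and KO normoxia replicate 1 short transcripts were high. The change in level per doubling of transcript length was -0.15 in WT hypoxia replicate 2 and -0.17 in KO normoxia replicate 1, against 0.16 in KO normoxia replicate 2 and 0.14 in KO hypoxia replicate 2. Small RNA genes (snoRNAs, Rpph1, Rmrp and others) took from 2.69% of the total in WT normoxia replicate 2 to 11.52% in KO hypoxia replicate 1. This share was higher in hypoxia than in normoxia for each number and genotype (3.68% to 6.63% and 2.69% to 6.23% in WT, 7.36% to 11.52% and 2.79% to 3.57% in KO). In WT both hypoxia libraries had slopes (-0.09 and -0.15) below those of both normoxia libraries (0.04 and 0.09).

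**Figure D1:**
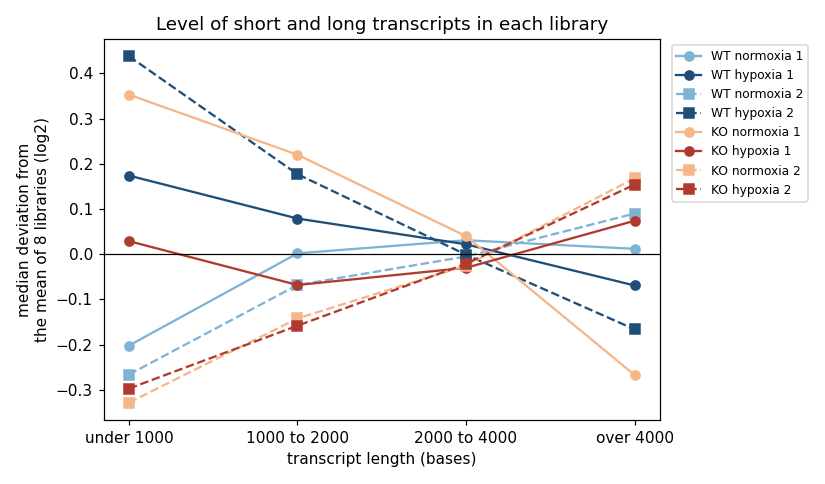
Median deviation of genes from their mean over the 8 libraries (log2, vertical axis) in 4 bins of transcript length in bases (horizontal axis). Each line is a library, coloured by group, with circles and solid lines for replicate 1 and squares and dashed lines for replicate 2. Transcripts in the shortest bin lay 0.44 above the mean in WT hypoxia replicate 2 and 0.35 above it in KO normoxia replicate 1, and at -0.33 in KO normoxia replicate 2.

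In WT cells hypoxia raised genes of the HIF programme. Slc16a3, the lactate exporter MCT4, rose from 14.0 ± 1.41 to 388 ± 77.8 normalised reads (log2 fold change 4.69 ± 0.41 SE, adjusted p = 0.00142). Egln3, a HIF prolyl hydroxylase, rose from 21.0 ± 7.07 to 433.5 ± 82.7 (4.33 ± 0.30, adjusted p = 4.7e-04), and Car9, a cell-surface carbonic anhydrase, by 3.91 ± 0.38 (adjusted p = 0.00247). Bnip3, a mitophagy receptor, rose by 3.13 ± 0.26 (adjusted p = 0.0014), and Pdk1, the kinase that holds back pyruvate dehydrogenase, by 3.27 ± 0.32 (adjusted p = 0.00247). Values before the adjusted p are log2 fold changes with their SE, from 2 libraries against 2. By limma 13 genes rose and 0 fell, with 766 of 12107 genes at an unadjusted p under 0.05 (605 by chance). The others that rose were Mgarp (4.44 ± 0.61), Ankrd37 (3.66 ± 0.33), Edn2 (3.18 ± 0.44), Fam162a (2.89 ± 0.38), Pfkl (2.29 ± 0.31), Ak4 (2.03 ± 0.26), Higd1a (1.90 ± 0.28) and Kdm3a (1.55 ± 0.23), with adjusted p from 0.00174 to 0.0432. Mgarp was near the floor in normoxia (2 and 1). The count was 1 (Egln3 alone) without WT hypoxia replicate 2, 6 without WT normoxia replicate 2, 7 without WT normoxia replicate 1, 8 without WT hypoxia replicate 1, and 20 without KO normoxia replicate 1 or without KO normoxia replicate 2. It was 6 with WT hypoxia replicate 2 and KO normoxia replicate 1 both left out.

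HIF-responsive genes rose as a group in WT. Of 40 tested, 9 rose over all genes and 33 adjusted over the list alone, 0 fell and 38 had a positive change, with a median of 1.17 (camera adjusted p = 5.9e-44, adjusted p = 0.0278 with an estimated correlation). Members that passed over the list alone include Bnip3l, a mitophagy receptor (1.44 ± 0.23), Ndrg1 (1.26 ± 0.25), Ddit4, an mTOR inhibitor (1.32 ± 0.27), and Vegfa, the angiogenic growth factor (0.96 ± 0.28). Glycolysis enzymes and transporters rose with a median of 1.32 (adjusted p = 6.2e-20). That call was lost at adjusted p = 0.351 with an estimated correlation. Of 20 glycolysis genes 3 rose (Slc16a3, Pdk1, Pfkl) and 15 adjusted over the list alone, among them Tpi1 (2.08 ± 0.34), Pgk1 (1.69 ± 0.29) and Ldha (2.05 ± 0.37). The HIF list shares 2 genes with the glycolysis list (Slc2a1, Pdk1), 3 with the collagen-modifying list and 2 with the autophagy list. Collagen-modifying enzymes were called up (median 0.09, mean 0.35, adjusted p = 0.0174, and adjusted p = 0.597 with an estimated correlation). Over that list alone 4 of 16 rose, the collagen hydroxylases P4ha1 (1.44 ± 0.23), P4ha2 (1.53 ± 0.28), Plod2 (1.36 ± 0.26) and Plod1 (1.07 ± 0.24). The call was lost without WT normoxia replicate 1 (median -0.12) or without WT hypoxia replicate 1 (0.21).

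Lists of short transcripts moved in WT hypoxia along with the level of short transcripts, which lay 0.17 and 0.44 above the mean in the hypoxia libraries (replicates 1 and 2) and at -0.20 and -0.27 in the normoxia libraries. Replication-dependent histones rose with a median of 0.98, 34 of 34 positive (adjusted p = 1.5e-16, adjusted p = 0.597 with an estimated correlation), and 1, Hist1h3b (1.49 ± 0.34), passed adjusted over the list alone. Subunits of oxidative phosphorylation (OXPHOS) rose with a median of 0.36 (70 of 74 positive, adjusted p = 1.2e-09, adjusted p = 0.805 with an estimated correlation), and cytosolic ribosomal proteins with a median of 0.38 (52 of 61 positive, adjusted p = 5.4e-09, adjusted p = 0.805 with an estimated correlation), with 0 members called in either list. With the trend of each library with transcript length removed, the calls for OXPHOS (median 0.04) and ribosomal proteins (0.08) were lost, while histones kept theirs (0.60). Both lists that follow fell. NRF2 targets had a median of -0.42 (17 of 22 negative, adjusted p = 9.7e-04, adjusted p = 0.351 with an estimated correlation), for example Nqo1 at -1.10 ± 0.37, and cholesterol biosynthesis a median of -0.26 (17 of 21 negative, adjusted p = 0.0136, adjusted p = 0.879 with an estimated correlation). The cholesterol call was lost without WT normoxia replicate 1 (-0.18) or WT hypoxia replicate 1 (-0.37). Collagens and ECM proteins fell with a median of -0.23 (29 of 35 negative, adjusted p = 0.0174, adjusted p = 0.879 with an estimated correlation), with Col4a2 at -0.60 ± 0.23. This call was lost without WT hypoxia replicate 1 (-0.08), with the length trend removed (-0.06), and without WT normoxia replicate 2, where the median turned to 0.10.

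**Figure D2:**
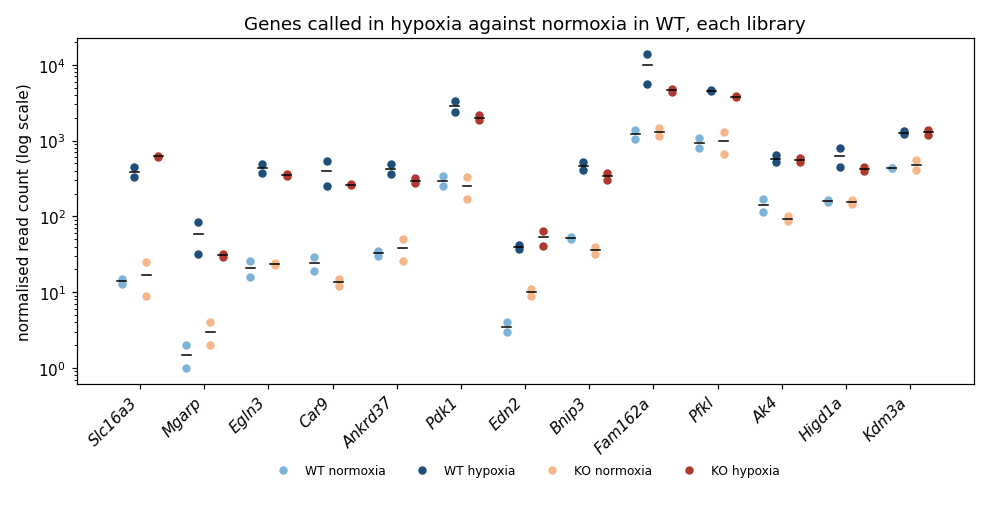
Normalised read counts (vertical axis, log scale) of the 13 genes called in hypoxia against normoxia in WT (horizontal axis). Points are the 2 libraries of each group, coloured by group, and black lines are group means. For each gene the hypoxia libraries lie above the normoxia libraries in WT and in KO, for example Slc16a3 at 333 and 443 against 15 and 13 in WT.

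In KO cells the same comparison, which asks whether the low-oxygen response is present in the cells named KO, raised 7 genes. Slc16a3 rose from 17.0 ± 11.3 to 620 ± 19.8 normalised reads (log2 fold change 5.27 ± 0.41 SE, n = 2 against 2, limma adjusted p = 7.1e-04). Car9 rose by 4.19 ± 0.38 (adjusted p = 0.00173), Egln3 by 3.86 ± 0.30 (adjusted p = 7.1e-04) and Bnip3 by 3.19 ± 0.26 (adjusted p = 7.8e-04). Pdk1 rose by 3.07 ± 0.32 (adjusted p = 0.00445), Ankrd37 by 2.99 ± 0.33 (adjusted p = 0.00644) and Ak4, a mitochondrial adenylate kinase, by 2.56 ± 0.26 (adjusted p = 0.0037). By limma 0 genes fell, and 387 of 12107 were at an unadjusted p under 0.05 (605 by chance). Without KO hypoxia replicate 2 the count was 4. It was 758 without KO normoxia replicate 2 (559 higher and 199 lower), with KO normoxia replicate 1 as the lone normoxic KO library.

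HIF-responsive genes rose as a group in KO, with a median of 1.21 and 39 of 40 positive (adjusted p = 2.7e-46, adjusted p = 0.0251 with an estimated correlation). Of these 6 rose over all genes and 27 adjusted over the list alone, such as P4ha1 (1.53 ± 0.23) and Adm, the vasodilator peptide adrenomedullin (1.47 ± 0.28). Glycolysis genes had a median of 0.98 (18 of 20 positive, 2 rose and 12 adjusted over the list alone, adjusted p = 3.9e-17). For glycolysis the adjusted p = 0.258 with an estimated correlation. Collagen-modifying enzymes rose with a median of 0.47 (adjusted p = 7.6e-05, adjusted p = 0.258 with an estimated correlation), with 6 of 16 passing adjusted over the list alone, among them Loxl2, a lysyl oxidase (1.77 ± 0.29), and Plod2 (1.36 ± 0.26). This call was lost without KO normoxia replicate 2 (0.61). Immediate-early genes rose with a median of 0.36 (15 of 19 positive, adjusted p = 0.015, adjusted p = 0.258 with an estimated correlation), with Klf2 at 1.35 ± 0.35, and their call was lost without KO normoxia replicate 2 (0.39) or KO hypoxia replicate 2 (0.35). Fry called this list in KO (adjusted p = 0.00175) and in WT (adjusted p = 0.0181), where camera did not (median 0.27, adjusted p = 0.141). Of the genes in that list 0 passed in KO, also adjusted over the list alone.

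Cholesterol biosynthesis fell in KO hypoxia with a median of -0.53 and 21 of 21 negative (adjusted p = 6.4e-09, adjusted p = 0.653 with an estimated correlation), for example Cyp51 at -0.77 ± 0.27, and the call was lost without KO normoxia replicate 1 (-0.12). NRF2 targets fell with a median of -0.31 (adjusted p = 4.5e-04, adjusted p = 0.258 with an estimated correlation), lost without KO normoxia replicate 2 (-0.22). Other lists were called beside the high level of short transcripts in KO normoxia replicate 1 (0.35 above the mean). OXPHOS subunits fell (median -0.22, 65 of 74 negative, adjusted p = 1.1e-05, adjusted p = 0.769 with an estimated correlation), as did ribosomal proteins (-0.19, adjusted p = 0.0019, adjusted p = 0.782 with an estimated correlation), histones (-0.26, adjusted p = 0.00368, adjusted p = 0.782 with an estimated correlation) and the genes flanking Mir210 (-0.19, adjusted p = 0.015, adjusted p = 0.769 with an estimated correlation). The direction of all 4 turned without KO normoxia replicate 1, with medians of 0.08, 0.12, 0.33 and 0.00. Without KO hypoxia replicate 2 the calls for ribosomal proteins (-0.11), histones (0.00) and the flanking genes (-0.23) were lost too, and without KO hypoxia replicate 1 that for the flanking genes (-0.12). With the length trend removed the calls for ribosomal proteins (-0.08), histones (-0.16) and the flanking genes (-0.15) were lost, as was that for ECM (0.18). Collagens and ECM proteins rose (0.30, 27 of 35 positive, adjusted p = 0.00368, adjusted p = 0.769 with an estimated correlation), as did contractile genes (0.22, adjusted p = 0.0138, adjusted p = 0.705 with an estimated correlation) and muscle markers (0.50, 9 of 9 positive, adjusted p = 0.0019, adjusted p = 0.54 with an estimated correlation). These medians were 0.10, 0.17 and 0.16 without KO normoxia replicate 1 and the calls were lost, and that for contractile genes was lost also without KO hypoxia replicate 1 (0.24) or KO normoxia replicate 2 (0.37). Of the members of the 7 lists, 0 passed adjusted over the list alone.

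**Figure D3:**
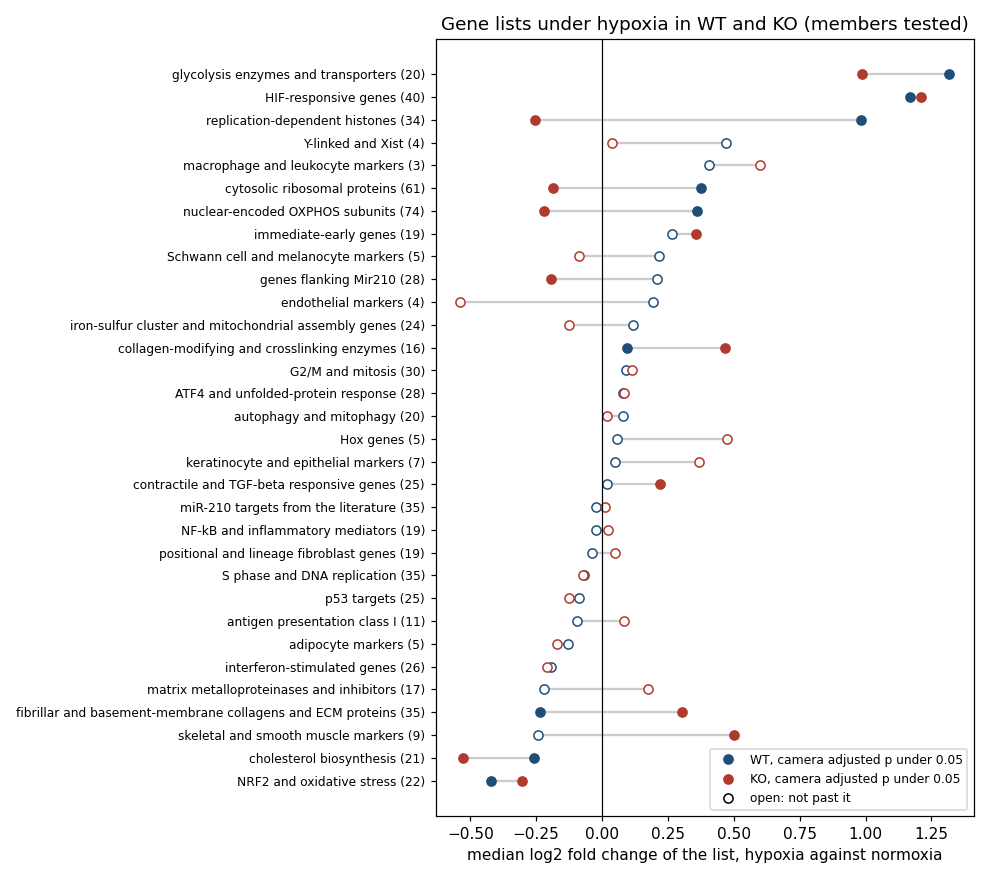
Median log2 fold change of each list, hypoxia against normoxia (horizontal axis), in WT (blue) and KO (red), with the number of tested members in brackets (vertical axis). Filled points passed camera with the preset correlation. HIF-responsive genes lie at 1.17 and 1.21, and histones at 0.98 and -0.26.

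The responses of WT and KO were then compared. All 7 genes called in KO were among the 13 called in WT, and all 13 had a positive change in both. Independent lists of these sizes would share 0.0075. Both tests use the same SE for a gene, so these lists are not independent and 0.0075 is not a chance level for them. Across the 12107 tested genes, the fold changes of WT and KO had a Pearson r of 0.16 and a Spearman rho of -0.01. Genes are not independent replicates. Across the 13 called genes, picked for their rise in these data, r was 0.84. Over all genes r was 0.49 without KO normoxia replicate 1, and without KO normoxia replicate 2 it was -0.07. For the 6 genes called in WT alone the difference of the responses was not past the test. Fam162a differed by -1.06 (95% confidence interval -2.24 to 0.12, adjusted p = 0.857) and Kdm3a by -0.12 (-0.83 to 0.60, adjusted p = 0.953). Over all genes limma called 0 differences, with 380 at an unadjusted p under 0.05 (605 by chance) and a smallest adjusted p of 0.857. That number of genes was above 605 without WT hypoxia replicate 1 or KO normoxia replicate 2, and below it without each other library. Among genes at or above the median value, those with the smallest p were Loxl2 (1.41 ± 0.41), Sorcs2 (1.10) and Cgnl1 (1.25), higher in KO, and, lower in KO, the ribosomal protein gene Rps25 (0.93 ± 0.27 in WT and -0.57 ± 0.27 in KO), Hist1h3b (-1.78 ± 0.49) and Pfdn4 (-1.23).

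HIF-responsive genes (median difference -0.05, adjusted p = 0.846) and glycolysis genes (-0.31, adjusted p = 0.167) were not called in the difference. Histones (-1.35, 34 of 34 negative, adjusted p = 9.3e-17), OXPHOS subunits (-0.61, 72 of 74 negative, adjusted p = 4.3e-15) and ribosomal proteins (-0.65, 56 of 61 negative, adjusted p = 1.2e-11) were lower in the KO response. Genes flanking Mir210 were also lower (-0.37, 22 of 28 negative, adjusted p = 0.00367), while collagens and ECM proteins (0.60, 29 of 35 positive, adjusted p = 9.0e-05) and muscle markers (0.69, 9 of 9 positive, adjusted p = 0.00362) were higher. Each of these 6 had adjusted p = 0.932 with an estimated correlation, and 0 of their members passed adjusted over the list alone. Histones, OXPHOS subunits and ribosomal proteins moved along with the length trend of WT hypoxia replicate 2 (-0.15 per doubling) and KO normoxia replicate 1 (-0.17). With that trend removed their medians were -0.78, -0.26 and -0.22, and of the 6 lists only the flanking genes lost their call. The call for collagens and ECM was lost without WT hypoxia replicate 1 (0.48) or WT normoxia replicate 2 (0.27), that for muscle markers without WT hypoxia replicate 2 (0.44), and that for the flanking genes without WT hypoxia replicate 1 (-0.44) or KO normoxia replicate 1 (-0.17), or with the length trend removed (-0.21). Over all settings histones ranged from -1.95 to -0.45, OXPHOS from -1.03 to -0.21 and ribosomal proteins from -1.04 to -0.19, called with the preset correlation in each.

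KO was compared with WT in normoxia to ask what differs before low oxygen is applied. By limma 0 genes passed, with 363 of 12107 at an unadjusted p under 0.05 (605 by chance) and a smallest adjusted p of 0.44. The unadjusted number was above 605 without KO normoxia replicate 2 and below it without any other single library. Values of the genes with the smallest p among those at or above the median value were 1455.5 ± 351 in KO against 459 ± 84.9 in WT for Cd34, a surface marker of stem cells and of some fibroblasts (log2 difference 1.65 ± 0.24, adjusted p = 0.44), 774 against 216 for Rian, an imprinted long noncoding RNA (1.88), and 0.87 for Vcam1. On the lower side they were the transglutaminase Tgm2 (-1.39 ± 0.26), Loxl2 (-1.23 ± 0.29) and Lmod1. Positional and lineage fibroblast genes were higher (median 0.18, 15 of 19 positive, 2 passing adjusted over the list alone, Cd34 and the retinoid-binding protein Crabp1 at 2.43 ± 0.58; adjusted p = 2.7e-04, adjusted p = 0.475 with an estimated correlation). Without WT normoxia replicate 1 that median was -0.01 and the call was lost.

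Lists of matrix and contraction were lower in KO normoxia. Collagens and ECM proteins had a median of -0.38 (31 of 35 negative, adjusted p = 8.8e-07, adjusted p = 0.527 with an estimated correlation), with the proteoglycan Dcn at -1.66 ± 0.44, and contractile genes -0.32 (23 of 25 negative, adjusted p = 2.1e-06, adjusted p = 0.475 with an estimated correlation), with Myl9 at -0.79 ± 0.25. Muscle markers (-0.61, adjusted p = 0.00308, adjusted p = 0.484 with an estimated correlation), metalloproteinases (-0.34, adjusted p = 0.00221, adjusted p = 0.527 with an estimated correlation; 1 passed over the list alone, Mmp23) and collagen-modifying enzymes (-0.15, adjusted p = 0.00491, adjusted p = 0.475 with an estimated correlation; 2 passed, Tgm2 and Loxl2) were lower too. NRF2 targets (-0.25, adjusted p = 0.019, adjusted p = 0.475 with an estimated correlation) and adipocyte markers (-0.71, 5 of 5 negative, adjusted p = 0.0234, adjusted p = 0.484 with an estimated correlation) were lower, and the Y-linked genes higher (0.65, 4 of 4 positive, 3 passing adjusted over the list alone, Eif2s3y, Uty and Kdm5d; adjusted p = 2.7e-04, adjusted p = 0.475 with an estimated correlation). Without WT normoxia replicate 2 the calls for ECM (-0.12), metalloproteinases (-0.29), collagen-modifying enzymes (-0.06) and adipocyte markers (-0.30) were lost. Without KO normoxia replicate 1 those for metalloproteinases (-0.21), adipocyte (-0.63) and muscle markers (-0.34) were lost, and without KO normoxia replicate 2 those for collagen-modifying enzymes (-0.10), NRF2 (-0.18), adipocyte markers (-0.79) and Y-linked genes (0.60). The NRF2 call was lost without WT normoxia replicate 1 as well (-0.15). With both WT libraries numbered 2 left out, the call for contractile genes was lost.

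Interferon-stimulated genes had a median of -0.67 in KO normoxia (23 of 26 negative, adjusted p = 2.3e-04, adjusted p = 0.744 with an estimated correlation). Among WT libraries they were high in those numbered 2: Ifi44 was at 64 in normoxia and 49 in hypoxia there, against 5 and 1 in those numbered 1. Some markers of other cell types were high in the same 2 libraries: the adipocyte genes Fabp4 (46 and 94, at most 13 in the other 6) and Lpl (84 and 56, at most 16), S100b (39 and 86, at most 22) and the endothelial gene Erg (31 and 24, at most 11). In hypoxia against normoxia this list was not called in WT (median -0.20, adjusted p = 0.379), KO (-0.21, adjusted p = 0.297) or the difference (0.03, adjusted p = 0.99), and its WT median was -1.02 without WT normoxia replicate 1 and 0.54 without WT normoxia replicate 2. In KO against WT the normoxia median turned to 0.09 without WT normoxia replicate 2, and without KO normoxia replicate 2 the call was lost (-0.61). Lists that moved with the short transcripts of KO normoxia replicate 1 (0.35 above the mean) were higher in KO normoxia: histones (0.53, 34 of 34 positive, adjusted p = 1.3e-09, adjusted p = 0.576 with an estimated correlation), OXPHOS subunits (0.17, adjusted p = 2.2e-04, adjusted p = 0.77 with an estimated correlation) and ribosomal proteins (0.24, adjusted p = 1.7e-04, adjusted p = 0.757 with an estimated correlation). Cholesterol biosynthesis (0.39, 20 of 21 positive, adjusted p = 2.4e-05, adjusted p = 0.595 with an estimated correlation) and G2/M genes (0.15, 24 of 30 positive, adjusted p = 0.00808, adjusted p = 0.77 with an estimated correlation) were higher as well. Without KO normoxia replicate 1 the medians of histones, OXPHOS, ribosomal proteins and cholesterol biosynthesis turned to -0.02, -0.10, -0.07 and -0.04. With the length trend removed the OXPHOS call was lost (0.08). Without WT normoxia replicate 2 the calls for OXPHOS (0.09) and ribosomal proteins (0.06) were lost and the G2/M median was -0.11, and it was -0.02 without KO normoxia replicate 2.

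In hypoxia, where miR-210 would be induced in WT, limma called 0 genes between KO and WT, with a smallest adjusted p of 0.29. Of 12107 genes, 910 were at an unadjusted p under 0.05 (605 by chance). This number was 2002 with array weights, where the smallest adjusted p in limma was 0.0541, and 752 with the length trend removed. It was below 605 without WT hypoxia replicate 2 or either KO hypoxia library. The genes with the smallest p at or above the median value were Mn1 (1.13), the pericyte proteoglycan gene Cspg4 (1.00 ± 0.23) and Cd34 (1.06 ± 0.24) on the higher side, and Bok (-0.97), Abracl (-0.95) and Pfdn4 (-1.07) on the lower. Literature targets of miR-210 were not called in any of the 5 comparisons. In hypoxia their median difference was 0.13 (21 of 35 positive, camera adjusted p = 0.435). Examples from the positive side, neither past the test, were E2f3 at 0.46 ± 0.27 and Gpd1l at 0.23 ± 0.23. In normoxia these 2 genes were at -0.29 ± 0.27 and -0.07 ± 0.23. The median of the list was -0.01 in normoxia (adjusted p = 0.949) and 0.05 in the difference of responses (adjusted p = 0.87). Under hypoxia it was -0.02 in WT (adjusted p = 0.831) and 0.01 in KO (adjusted p = 0.857). Genes flanking Mir210 were lower in KO hypoxia (-0.40, 23 of 28 negative, adjusted p = 2.5e-04, adjusted p = 0.738 with an estimated correlation), with Rassf7 at -1.01 ± 0.24 and Taldo1 at -0.66 ± 0.22, and 0 passed adjusted over the list alone. In normoxia this list had a median of 0.00 (adjusted p = 0.906).

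Positional and lineage fibroblast genes were higher in KO hypoxia (0.34, 16 of 19 positive, adjusted p = 0.00189, adjusted p = 0.738 with an estimated correlation). Over that list alone 3 passed, Dlk1, an imprinted Notch-family ligand (2.20 ± 0.43), Cd34 and the limb transcription factor Tbx3 (1.82 ± 0.52), and the call was lost without WT hypoxia replicate 1 (0.10). Histones (-0.77, 34 of 34 negative, adjusted p = 4.3e-08), OXPHOS subunits (-0.39, 72 of 74 negative, adjusted p = 1.5e-10) and ribosomal proteins (-0.39, 56 of 61 negative, adjusted p = 1.3e-07) were lower, beside the short transcripts of WT hypoxia replicate 2 (0.44 above the mean). Each of these 3 had adjusted p = 0.738 with an estimated correlation, and with the length trend removed the calls for OXPHOS (-0.11) and ribosomal proteins (-0.09) were lost. Interferon-stimulated genes were lower (-0.71, 22 of 26 negative, adjusted p = 0.0058, adjusted p = 0.738 with an estimated correlation), and without WT hypoxia replicate 2 their median turned to 0.10.

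Genes with a miR-210 seed site were compared with genes without one to ask whether likely targets are higher in KO. Of 11432 genes with a searched 3' UTR, 431 held a site, and their UTRs were longer (median 2799 bases against 1193). In hypoxia their median difference between KO and WT lay 0.17 above that of genes without a site (camera adjusted p = 0.00152, p = 0.168 with an estimated correlation), and in the difference of responses 0.22 above it (adjusted p = 0.00111, p = 0.142 with an estimated correlation). In normoxia the difference was -0.05 (adjusted p = 0.209). Against 1804 genes matched on UTR length camera gave 0.07 in hypoxia (p = 0.187, n = 431 genes with a site) and 0.07 in the difference of responses (p = 0.287, n = 431). Without WT hypoxia replicate 2 the value in hypoxia was 0.10, and that in the difference of responses was 0.12 without KO normoxia replicate 1 and 0.36 without KO normoxia replicate 2. The normoxia value was -0.17 without KO normoxia replicate 2.

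The other lists were not called in any of the 5 comparisons. Their medians in WT and in KO hypoxia were 0.12 and -0.13 for iron-sulfur cluster and mitochondrial assembly genes, -0.07 and -0.07 for S phase, -0.09 and -0.13 for p53 targets (Plk3 -0.68 in both), 0.08 and 0.08 for ATF4 and the unfolded-protein response, 0.08 and 0.02 for autophagy, -0.09 and 0.08 for antigen presentation, -0.02 and 0.02 for NF-kB mediators, and 0.06 and 0.47 for the 5 Hox genes tested. In autophagy 1 gene rose in each (Bnip3), and 2 adjusted over the list alone (Bnip3 and Bnip3l). In lists that were not called, 1 member each passed adjusted over the list alone for Vegfa in ATF4 and the unfolded-protein response (KO hypoxia, 1.42 ± 0.28), Vcam1 in NF-kB mediators (KO against WT in normoxia, 0.87 ± 0.21), and, for KO against WT in hypoxia, Mmp23 in metalloproteinases (-2.37 ± 0.45) and Cspg4 in muscle markers (1.00 ± 0.23). Of the 10 endothelial, 12 leukocyte and 8 Schwann cell or melanocyte markers listed, 0 had a mean value of 100 or more, and of 17 keratinocyte markers 2 did (Perp at 827.8 and Krt19 at 169.1). Of 6 adipocyte markers 1 did (Pparg at 245.8), and of 14 skeletal and smooth muscle markers 7 did, among them Cspg4 at 1219 and Mcam at 755.8. Medians in WT and KO hypoxia were 0.40 and 0.60 for leukocyte (3 genes tested) and 0.19 and -0.54 for endothelial markers (4 tested). They were 0.05 and 0.37 for keratinocyte (7 tested) and 0.21 and -0.09 for Schwann and melanocyte markers (5 tested). The leukocyte and endothelial markers had values of at most 48 in any library, so these medians rest on few genes with few reads. In 16 of the 160 tests of a list the median and the mean differed in sign, and in 15 the median and the test, and 0 of the 49 calls were among them. With an estimated correlation 2 of the 49 calls held, HIF-responsive genes in WT and in KO.

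With both genotypes pooled, a comparison added after the data were seen, limma called 44 genes up and 0 down under hypoxia, with 641 at an unadjusted p under 0.05. Of the 44, 23 are in the HIF list and 30 in the HIF or the glycolysis list. They include the glycolytic enzymes Tpi1 (1.61 ± 0.24), Pgk1 (1.53 ± 0.20) and Ldha (1.51 ± 0.26), the collagen hydroxylases P4ha1 (1.49 ± 0.17) and Plod2 (1.36 ± 0.19), Vegfa (1.19 ± 0.20), the peptide Apln (1.30 ± 0.18) and Ndufa4l2, a HIF-induced mitochondrial protein (3.68 ± 0.55). The count ranged from 12 without WT hypoxia replicate 2 to 50 without KO normoxia replicate 1, and was 14 without KO hypoxia replicate 1, 17 without WT normoxia replicate 2, 20 without WT normoxia replicate 1, 26 without WT hypoxia replicate 1 and 26 without KO hypoxia replicate 2. KO against WT over both oxygen levels called 3 genes, each at adjusted p = 0.0436 in limma. Cd34 was higher in KO (1.36 ± 0.17), as was Meg3, an imprinted long noncoding RNA (1.87 ± 0.23), and Glipr1, a secreted cysteine-rich protein gene, was lower (-1.96 ± 0.22). Over the settings run Cd34 ranged from 1.22 to 1.48, Meg3 from 1.69 to 2.07 and Glipr1 from -2.13 to -1.67. The test treats the 4 libraries of a genotype as independent. Differences between replicates, however, correlated across genes at 0.57 between the WT groups and 0.23 between the KO groups. The p values may therefore be too small. Cd34, Meg3 and Glipr1 each separated 4 of 4 KO from 4 of 4 WT libraries, which may stand for fewer independent samples. Without any 1 of the 8 libraries this count was 0, and without a filter on low values it was 0.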

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

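The test of seed sites against other arrangements of the bases, those on genes matched for UTR length and those with the length trend removed were written before their own values were known, but the seed-site pattern, like the length correction and the removal of 2 libraries, was chosen after the result was seen.

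The hypoxia responses of WT and KO differed for 6 lists in a test of the difference itself, as given in the report: replication-dependent histones (-1.35), ribosomal proteins (-0.65), OXPHOS subunits (-0.61), genes flanking Mir210 (-0.37), muscle markers (0.69) and collagens and ECM proteins (0.60). Genes with a miR-210 seed site also differed from those without (0.22), a call lost with an estimated correlation (p = 0.142, n = 431), against genes matched on UTR length (0.07) and with the length trend removed (0.04). None of the 6 lists passed with an estimated correlation (adjusted p = 0.932 each). The flanking, muscle and ECM lists were not weighed further.

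Histones, OXPHOS subunits and ribosomal proteins were called up in WT hypoxia and down in KO hypoxia with the preset correlation alone (adjusted p = 0.597, 0.805 and 0.805 in WT and 0.782, 0.769 and 0.782 in KO with an estimated correlation), and their transcripts are short (median 625, 913 and 964 bases against 3156 over all genes). With each library's trend with transcript length removed, the median of the 3 list medians was -0.26 in place of -0.65, yet the 3 lists still passed with the preset correlation (histones -0.78, OXPHOS -0.26, ribosomal proteins -0.22), so the trend may account for part of the difference and the test does not settle the rest. Without KO normoxia replicate 1 and WT hypoxia replicate 2 together the median was -0.21, under 0.5 of its size. The KO medians were then above 0 (0.33, 0.08 and 0.12), so the opposite directions depend on these libraries. Short transcripts were highest in these 2 libraries, so for lists that follow them the removal shrinks the difference whatever its source. Without KO normoxia replicate 2 the KO medians were lower instead (-0.83, -0.58 and -0.56). For the explanation that genotype changes the hypoxia response, the medians over the 169 members were 0.21 and 0.78 in the WT pairs of like number, and -0.49 and 0 in the KO pairs. The value 0 met the bound set beforehand against this explanation (at least 1 pair within 0.2 of 0), but each pair rests on 1 library per side and the KO pairs lie further apart (-0.49 and 0) than that margin of 0.2, so genotype is left open, a reading chosen after the value was seen.

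Genes with a seed site were higher in KO than in WT in hypoxia by 0.17, and have longer 3' UTRs. The difference was 0.07 against genes matched on UTR length and 0.01 with the length trend removed, each under 0.5 of the uncorrected value, in line with long UTRs and the trend between libraries as sources of it. Loss of repression by miR-210 predicts that its site stands out among other arrangements of the same bases: by length-matched difference it ranked 19 of 60 (0.07, against a median of 0.06 and a highest of 0.12). All 60 had a positive difference before matching. The rank was neither among the 3 highest nor at or below the median, so a small effect of miR-210 could not be told apart from none.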

How the results depend on the processing

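Tests with the length trend removed, with KO normoxia replicate 1 and WT hypoxia replicate 2 left out (both libraries in doubt), with both WT libraries numbered 2 left out, with a block within genotype, without small RNAs and with a pseudocount of 0 were chosen after the data were seen, as were both pooled comparisons. The planned count test was not run, since whole reads could not be recovered from rounded values. Where a setting left a group with 1 library, that library was assumed to vary like the other groups. Unless stated, the cause was not tested.

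Of the genes called under hypoxia in WT (13), the count was 6 without a filter (more genes tested), 21 with array weights, 22 with the length trend removed, 6 with both libraries in doubt left out, 0 with both WT libraries numbered 2 left out (fewer samples) and 7 with only the 4 libraries compared. In KO (7) it was 14 with the length trend removed, 2 with both WT libraries numbered 2 left out and 2 with only the 4 libraries compared. Pooled hypoxia (44) gave 24 without a filter, 25 with both libraries in doubt left out and 3 with both WT libraries numbered 2 left out. Pooled KO against WT (3) gave 0 without a filter, 0 with a stricter filter, 6 with the length trend removed, 0 with both libraries in doubt left out and 0 with both WT libraries numbered 2 left out. The correlation of the responses (0.16) was 0.47 with both libraries in doubt left out. The named genes kept their sign in the settings run, except Dio3 in pooled KO against WT (0.15, from -0.34 to 1.10): in WT Slc16a3 ranged from 4.36 to 4.89 and Egln3 from 4.00 to 4.66, and in KO Car9 from 3.86 to 4.34.

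With the replicate number as a block, limma called 19 genes in WT, 11 in KO and 0 in the other planned comparisons. With a block within each genotype it called 230 in WT (221 higher and 9 lower) and 57 in KO (54 higher and 3 lower). Pooled over genotypes that block gave 243 (228 higher and 15 lower). Without a block 0 genes were lower under hypoxia in WT, in KO and pooled. Differences between replicates correlated across genes at 0.57 between WT normoxia and WT hypoxia and 0.23 between the KO groups, but at 0.11 (WT and KO normoxia) and 0.02 (WT and KO hypoxia) across genotypes, so libraries of like number deviate together within a genotype, more so in WT. In WT the number thus goes with a difference shared by the normoxia and hypoxia libraries, which the model without a block leaves in the spread. In KO this is less clear. The labels do not say what a number marks, and the main model was planned without a replicate term, so the blocked values are given here alone. With the block within each genotype the difference of responses still called 0 genes, with 1316 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0918 in place of 0.857.

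Leaving out each library in turn gave 1 to 20 genes in WT, 4 to 758 in KO, 12 to 50 pooled over genotypes and 0 to 0 for pooled KO against WT, KO against WT in normoxia, in hypoxia and the difference. The correlation of responses ranged from -0.07 to 0.49. In each comparison the genes at an unadjusted p under 0.05 numbered above 605 without some library and below it without another. Set against the 605 expected by chance, these numbers therefore decide nothing. Lists called ranged from 8 to 15 in WT, 7 to 13 in KO, 9 to 16 for KO against WT in normoxia, 6 to 9 in hypoxia and 5 to 11 for the difference. Seed sites ranged from -0.17 to 0.05 in normoxia, 0.10 to 0.18 in hypoxia and 0.12 to 0.36 in the difference.

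With an estimated correlation 1 list was called in WT, 1 in KO, 0 for KO against WT in normoxia, 0 in hypoxia and 0 for the difference, and with fry 2, 2, 0, 0 and 0. The KO count was 6 with both libraries in doubt left out, and the normoxia count 7 with both WT libraries numbered 2 left out. Seed sites lost their call in hypoxia with an estimated correlation (0.17), matched on UTR length (0.07) and with the length trend removed (0.01), and in the difference with an estimated correlation (0.22), 8-mer sites (0.16, fewer genes), matching (0.07), the length trend removed (0.04) and both libraries in doubt left out (0.06).

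Lists whose tested direction reversed follow, with the range over the libraries left out in turn. In WT hypoxia ECM ranged from -0.74 to 0.10 (without WT normoxia replicate 2), and interferon from -1.02 to 0.55 (without WT hypoxia replicate 1), with 0.54 without WT normoxia replicate 2. In KO hypoxia ribosomal proteins ranged from -0.56 to 0.12, genes flanking Mir210 from -0.49 to 0.00, OXPHOS from -0.58 to 0.08 and histones from -0.83 to 0.33, from without KO normoxia replicate 2 to without KO normoxia replicate 1, and the higher values held with both libraries in doubt left out. For KO against WT in normoxia the same libraries gave 0.80 to -0.04 for cholesterol, 0.61 to -0.07 for ribosomal proteins, 0.47 to -0.25 for glycolysis, 0.51 to -0.10 for OXPHOS and 1.18 to -0.02 for histones, the negative values also with both libraries in doubt left out, and -0.35 (without KO normoxia replicate 1) to 0.24 for flanking genes. There G2/M ranged from -0.11 (without WT normoxia replicate 2, and with both WT libraries numbered 2 left out) to 0.44, and was -0.02 without KO normoxia replicate 2. Interferon in normoxia ranged from -1.44 to 0.09 (without WT normoxia replicate 2) and was 0.05 with both WT libraries numbered 2 left out. In hypoxia it ranged from -1.44 to 0.10 (without WT hypoxia replicate 2, and with both libraries in doubt left out) and was 0.06 with both WT libraries numbered 2 left out. In the difference interferon ranged from -0.72 to 0.73 (without WT normoxia replicate 1), with 0.67 without WT hypoxia replicate 2 and 0.55 with both libraries in doubt left out. Medians of called lists reached the other side of 0, or 0.00, with the tested direction kept and the call lost for collagen-modifying enzymes in WT hypoxia (-0.12 without WT normoxia replicate 1), positional fibroblast genes in normoxia (-0.01 without WT normoxia replicate 1) and histones in KO hypoxia (0.00 without KO hypoxia replicate 2). The estimated depth of 6.26 M to 11.74 M reads limits genes near the minimum of 10, where a value rests on about 10 reads.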

Other observations

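The genes of the Dlk1-Dio3 region were chosen after their values were seen, as were the test of loss of miR-210 or a difference between the cell lines, the follow-up on lengths among other splits of the libraries, and the splits with the length trend removed.

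In the imprinted Dlk1-Dio3 region on chromosome 12 (GRCm38, Dlk1 from 109452823 and Mirg to 109749460, an interval that does not take in Dio3), 1 of 5 tested genes, Meg3, passed in KO against WT over both oxygen levels (1.87, limma adjusted p = 0.0436). Values of the others were Dlk1 1.80 (adjusted p = 0.18), Rian 1.36 (adjusted p = 0.365), Mirg 1.24 (adjusted p = 0.394) and Dio3 0.15 (adjusted p = 0.986), and no list test was run on genes picked for their values. With 1 library left out, their median of 1.36 lay between 1.13 (without WT hypoxia replicate 1) and 1.68 (without WT hypoxia replicate 2). It was 1.24 with the length trend removed. The median of these genes thus stayed positive in each of these settings. Since the genes were picked for being higher in KO, these values cannot decide whether a lone library or that trend is a source of it. The lowest KO library lay 0.3 above the highest WT library, but on genes picked for being higher in KO this decides nothing. Loss of miR-210 or a difference between the cell lines cannot be told apart, since each genotype is its own set of cultures.

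For the pooled comparisons all 35 splits of the 8 libraries into 4 and 4 were run in a model of 2 groups. The oxygen split gave 48 genes and 2 of the 35 splits gave as many, itself and a split with 135 genes, the highest, so by this count alone chance cannot be excluded. That other split points to a structure of the libraries: it parts those with length slopes of 0.035 and above from those at -0.018 and below. It also parts those with a small RNA share of 3.68% and below from those at 6.23% and above, and these traits cannot be told apart here. Its genes had a median length of 131 bases against 3156 over all tested genes. With the length trend removed it gave 0 genes, while the oxygen split gave 60 and no other split more than 6. In that setting 1 of the 35 (2.9%) gave as many, the oxygen split itself. That is the smallest share that 35 splits can give. The setting was chosen after the 135 genes were seen and takes out a trend that parts that split, so it does not exclude chance. The genotype split gave 1 gene and 3 of the 35 gave as many (highest 135). Among these 3 is the oxygen split, the other factor of the design. By that count chance cannot be excluded for genotype. With the length trend removed it gave 6, and of the others the oxygen split gave 60 and the remaining 33 gave 0. So 2 of the 35 (5.7%), the oxygen and the genotype split, gave as many as genotype. The oxygen split is a factor of the design and not a split by chance. With it among the 35, the share for genotype could not fall below 5.7%. The share therefore cannot decide on chance, and the setting was chosen after the data were seen, so chance is not excluded.

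snoRNAs (107 tested) were higher in hypoxia in each pair of like number, by medians of 1.36 and 1.00 in WT and 1.11 and 0.42 in KO. Other small RNAs (49) were at 0.61 and 0.61 in WT and 0.55 and 0.17 in KO. These classes were looked at after the data were seen, the labels do not say what a number marks, and no explanation was tested.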
